A study of Caenorhabditis elegans with 2 samples.

How the data were processed

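ChIP-seq against GFP-tagged SNPC-4 was done by the authors in whole young adult worms of strain YL457, both sexes pooled, in 2 replicates that the labels number as biological. Per the labels, the strain carries an integrated transgene with unc-119(+) in which the pie-1 promoter drives the fusion; another label describes a C-terminal GFP-FLAG tag, and the labels do not settle between the descriptions. Per the labels, chromatin was sheared by sonication. The authors deposited 8 peak lists: for each of the builds ce10 and ce11, a list per replicate, a list called on both replicates pooled, and a thresholded set. Per the deposited text records, the pooled and replicate lists are peaks and background regions made as input for an irreproducible discovery rate (IDR) step, and a control alignment was used. The aligner, peak caller, versions and IDR threshold are not given in the sources used here, and no control library was used here.

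Each peak has a signal value, a −log10 of the q-value and a summit offset, as deposited. The signal is the authors' own value per peak; its scale is not given in the sources used here, so it was used only to rank and describe peaks within a list. Beside a pooled signal, the mean ± SD over the replicates is that of the matched peaks in the replicates' own lists, whose scale may differ from the pooled one. The deposited −log10 q-value has a ceiling, shared by 4814 of the 30000 pooled peaks on ce11. The thresholded set was checked to be identical to the 1648 pooled peaks with the highest signal on ce11, and to the 1614 highest on ce10, so any loosening of the threshold follows the signal. Read numbers are not in the lists; depth and the errors that depend on it are unknown, and the exact binomial intervals at 95% cover counting error over genes or peaks.

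Genes and sequence came from the WBcel235 assembly (the same as ce11) with the Ensembl 115 annotation of 46926 genes; coordinates are 1-based. U1, U2, U4, U5 and U6 genes were recognised among annotated snRNA genes by a conserved core of their sequence, SL1, SL2 and SmY RNA genes by name, and annotated snRNA genes without a core formed their own class. A gene was bound when the summit of a thresholded peak lay within 500 bp of its annotated start. For error, the same count was made with the 1648 strongest peaks of each replicate. Bound counts were compared with 10000 circular shifts of all peaks within their chromosomes, one-sided, adjusted by Benjamini-Hochberg over 17 classes. Where a peak is given 1 class, snRNA, SL RNA and SmY RNA genes came first, then the other short noncoding classes, then protein-coding and other genes.

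Peaks per chromosome were compared with chromosome length by exact binomial tests. The ce11 lengths also stood in for ce10, whose sequence was not used here. The piRNA clusters were regions of at least 1 Mb on IV made of 100 kb bins with at least 50 piRNA genes, bins less than 300 kb apart joined, and were tested against 10000 random placements on IV. Signal by class was tested by 100000 permutations of class labels over peaks, for classes with at least 5 peaks. Summit positions are those of the nearest summit, except in the histograms and for single named genes, where they are those of the strongest summit in the window. Octamers were counted within 100 bp of the summit and in windows 500 to 700 bp away, on alternating sides, with exact McNemar tests. Fixed gene lists were compared with all other protein-coding genes by Fisher's exact test. Replicates were matched by summits within 200 bp. The correlation has a bootstrap interval from 1000 draws over peaks.

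The tests, the alternatives and the rule for named genes were fixed before the data were examined. The alternatives were other windows, any overlap, a stricter threshold, each replicate alone, merged neighbours, random placement, omission of the piRNA clusters, the other build, and other match distances. The rule named the 20 strongest peaks by the gene with the nearest start, the 3 bound genes of highest signal in each class, the unbound members of classes with fewer than 15 members, up to 5 bound genes per list, and unc-119, pie-1 and snpc-4. Chosen after the data were seen were the alternatives that leave out the mitochondrial genome or the peaks at tRNA or other short noncoding genes, the looser threshold at the q-value ceiling, and the octamer scans of subsets of peaks. Of the lists, the intestine, body wall muscle, neuron, and hypodermis and collagen genes are markers of other tissues that a whole animal holds.

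The statistics on classes, chromosomes, clusters, signal, summit positions, octamers, lists and matched replicates were first tested on simulated data. With nothing planted, 0 of 170 class tests in 10 simulated lists, 0 of 60 chromosome tests, 0 of 14 signal classes and 0 octamers over 600 simulated peaks were called. For classes, chromosomes and octamers the simulated peaks were placed independently and at random, so peaks that cluster like the real ones were not covered. Of 100 genes with a planted summit 100 were found bound among 46926 genes, and a planted list of 12 genes was called while 0 other lists were. The correlation and the tests of explanations were run on simulated data only after their results had been seen, and those results did not change. There, 0 of 10 sets of copies with nothing planted were called by the permutation, with simulated copies that were independent of each other. The upstream element was found at 100 of 100 summits where it was planted and at 7 of 500 others. The planted element varied less than the real one, so this says little about how many real elements are found. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, and the random seed was 20.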

Results

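SNPC-4 is the worm orthologue of SNAP190, the large subunit of the snRNA-activating protein complex (SNAPc), which binds upstream of small nuclear RNA (snRNA) genes. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole young adult Caenorhabditis elegans of both sexes. The animals were of strain YL457, which carries a GFP-tagged copy of the protein on an integrated transgene. The series holds 1 group of 2 replicates, which the labels call biological, and no further condition, so bound places were compared with the rest of the genome. The 1648 thresholded peaks that the authors derived from both replicates on the ce11 build covered 0.517 Mb, with a median width of 350 bp. Each replicate was also given as its own list of 30000 peaks. The sequencing depth of the replicates is unknown, and intervals cover counting error over genes or peaks only.

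SL2 RNA, U1, U5, U4 and SmY RNA genes had the highest bound shares of the 17 gene classes tested. A peak summit lay within 500 bp of the start of 17 of 18 SL2 RNA genes, which encode the spliced leader of downstream genes in operons (94.4%, 95% exact binomial interval 72.7 to 99.9%). For SmY RNA genes, whose products associate with spliced leader RNA particles, the count was 8 of 10 (80%, 44.4 to 97.5%). Of the spliceosomal snRNA genes, 11 of 13 U1 genes (84.6%, 54.6 to 98.1%), 10 of 12 U5 genes (83.3%, 51.6 to 97.9%) and 4 of 5 U4 genes (80%, 28.4 to 99.5%) were bound. For U2 and U6 genes the counts were 10 of 20 (50%, 27.2 to 72.8%) and 8 of 23 (34.8%, 16.4 to 57.3%). No peak stood at the 12 SL1 RNA genes, near-identical copies for which this count sets no limit on binding.

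Replicate 1 and replicate 2, each by its own 1648 strongest peaks, bound 17 and 17 SL2 RNA genes, 11 and 9 U1 genes, 10 and 10 U5 genes, 8 and 7 SmY RNA genes, 11 and 9 U2 genes and 8 and 8 U6 genes. Over the replicates the bound share was 76.9% ± 10.9 for U1 genes and 50% ± 7.07 for U2 genes (SD, n = 2). Against 10000 circular shifts of all peaks along their chromosomes, the bound count was 76.8 times the shifted mean for U1, 72.7 times for U4, 53.9 times for SL2 RNA, 38.4 times for SmY RNA, 34.9 times for U5, 34.2 times for U2 and 17.6 times for U6 genes. Each of these 7 classes had a one-sided permutation p of 0.0001, the smallest the shifts can give, and an adjusted p of 0.000155 (Benjamini-Hochberg over 17 classes). The fold depends on the window and the threshold: for U1 genes it was 156 with 250 bp, 42.5 with 1000 bp and 162 with the 824 strongest peaks, and the other 6 classes moved alike. With the piRNA clusters left out it was 78.9 for U5 genes, and 2 of the remaining 4 SmY RNA genes were bound (45.4 times, adjusted permutation p = 0.00227). The SL1 RNA genes gave a one-sided p of 1.

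In the U1, U4, U5 and SmY RNA classes, the unbound members were U1 genes T27E4.10 and T27E4.11 on V, U4 gene T11F9.16 on V, U5 genes C53B4.9 and C53D6.16 on IV, and smy-4 and smy-5 on V. The unbound SL2 RNA gene was sls-2.6 on I. The 12 unbound SL1 RNA genes, 10 of them annotated as sls-1.10 and 2 as sls-1.1, lay between 17118154 and 17132107 on V (ce11). The sequence around the start of the median SL1 RNA gene held 0% unique words of 32 bases, against 89.6% at bound SL2 RNA genes. The unbound U1 genes T27E4.10 and T27E4.11 also held 0%, against a median of 90.4% at bound U1 genes, and at U6 genes the medians were 89.8% for bound and 45.9% for unbound members. In other classes unbound members had higher medians than bound ones: 100% against 89.6% for SL2 RNA, 98.7% against 91.9% for U5, 92.6% against 91.3% for U4 and 77.4% against 73.5% for U2 genes. For SmY RNA genes the medians were 100% for bound and 92.4% for unbound members. A further 2 of 16 annotated snRNA genes without a recognised U core were bound, 8.71 times the shifted mean (one-sided permutation p = 0.0208, adjusted p = 0.0272). One was M163.13 on X, with a signal of 164, and the other an annotated locus named mir-1831, which lies inside the U1 gene sup-39 and shares its peak. With a window of 1000 bp this class was 4.42 times the shifted mean and did not pass (adjusted permutation p = 0.109).

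**Figure D1:**
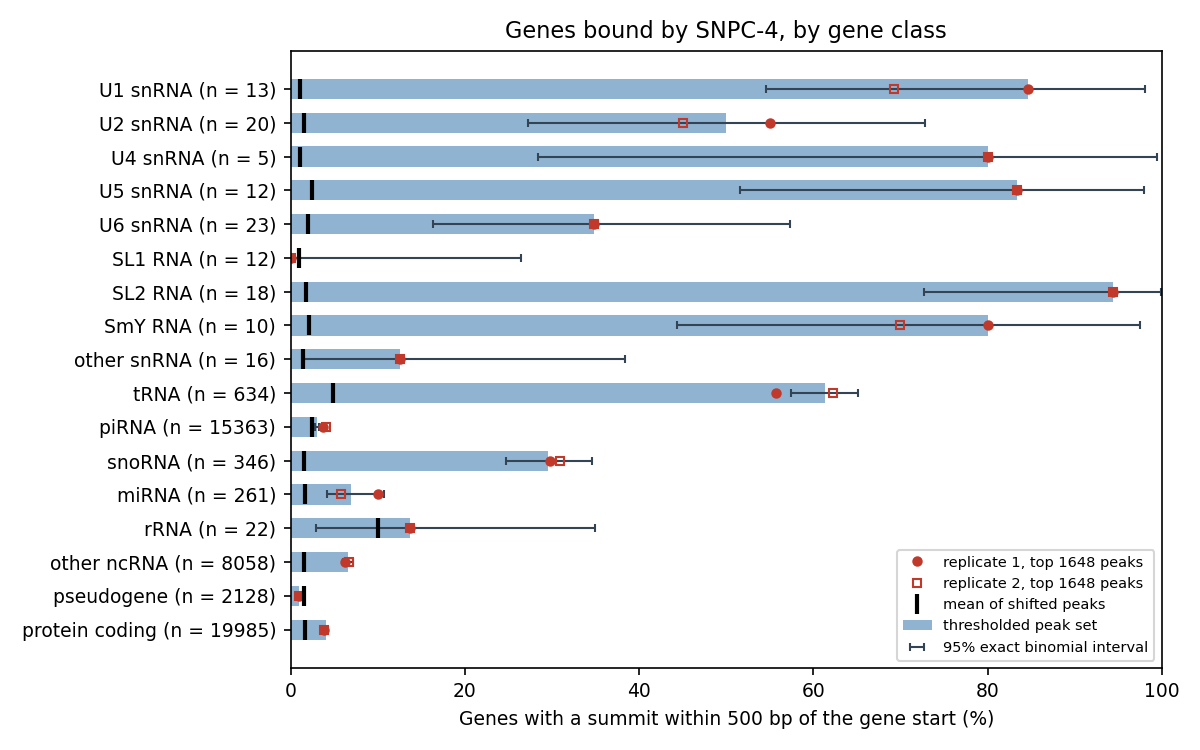
Bound share of each gene class, in percent of its genes with a peak summit within 500 bp of the gene start; bars are the 1648 thresholded peaks with 95% exact binomial intervals, red marks are the 2 replicates by their own strongest 1648 peaks, and black ticks are the mean of 10000 circular shifts. SL2 RNA genes stand at 94.4%, tRNA genes at 61.4%, snoRNA genes at 29.5%, protein-coding genes at 4.04% and SL1 RNA genes at 0%.

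Genes of transfer RNA (tRNA) and small nucleolar RNA (snoRNA) also carried peaks. Of 634 tRNA genes, 389 were bound (61.4%, 57.4 to 65.2%), and the replicates gave 59.0% ± 4.68 (SD, n = 2). Of the 346 snoRNA genes, whose RNAs guide modification of other RNAs, 102 were bound (29.5%, 24.7 to 34.6%), with 30.3% ± 0.817 over the replicates (SD, n = 2). Of 261 microRNA genes 18 were bound (6.90%, 4.14 to 10.7%), with counts of 26 and 15 in the replicates. Of 22 ribosomal RNA genes 3 were bound, of which rrn-4.15 on V, a gene of the 5S family, was the nuclear one, with a signal of 142. Pseudogenes were bound in 20 of 2128 cases (0.940%, 0.575 to 1.45%).

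The tRNA count was 12.5 times the shifted mean and the snoRNA count 18.9 times (both one-sided permutation p = 0.0001, the smallest possible, adjusted p = 0.000155). Of the tRNA genes, 612 are nuclear, and 367 of these were bound (60.0%). Without the mitochondrial genome, where peaks lie so densely that shifted summits hit its genes too, the tRNA fold was 37.7 and the rRNA fold went from 1.36 (adjusted permutation p = 0.219) to 4.39 (p = 0.224), passing in neither case. MicroRNA genes were at 4.18 times the shifted mean (adjusted permutation p = 0.000425) and pseudogenes at 0.640 times (one-sided p = 0.984). Other noncoding genes, 527 of 8058 bound, were at 4.20 times the shifted mean (adjusted permutation p = 0.000155). Of these 527 genes, 328 (62.2%) shared their peak with the start of a short noncoding gene, and against the peaks away from such starts the fold was 2.69 (adjusted permutation p = 0.000567).

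The strongest nuclear peaks stood at snoRNA and SL2 RNA genes. Peak strength is the authors' own signal value per peak, which serves here to rank peaks within the pooled list. The snoRNA gene Y53F4B.47 (II, 15025814 to 15025893) led with a signal of 1639 and 833 ± 28.4 over the replicates' own lists (SD, n = 2). It was followed by sls-2.1 (II, 5844865 to 5844974) at 1429, with 724 ± 92.6, and by the snoRNA genes C16D9.11 (V, 8228900 to 8228969) at 1367, with 682 ± 122, and W04D2.7 (V, 12491280 to 12491346) at 1360.0, with 669 ± 185 (SD, n = 2 each). The list went on with noncoding gene Y37E3.29 at 1297, snoRNA gene C08D8.3 at 1221, sls-2.8 at 1179.6, snoRNA gene ZK994.7 at 1127, sls-2.4 at 1104, snoRNA gene F01D5.12 at 1065 and the U6 gene R07E5.16 (III, 10989679 to 10989780) at 1042. Noncoding gene T06D8.17 stood at 989, snoRNA genes F59C6.15, T26A8.6 and Y55F3BR.9 at 945, 939.5 and 907, and rpr-1, the RNA component of RNase P, at 871. The noncoding genes Y37E3.29 and T06D8.17 lie within 500 bp of the snoRNA genes Y37E3.20 and T06D8.11.

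The other 4 of the 20 strongest peaks lay in the mitochondrial genome, with signals of 6864, 3097, 2944 and 946. They were nearest to the starts of the protein-coding genes WBGene00000829, WBGene00010967 and WBGene00010961 and the tRNA gene WBGene00014473. The mitochondrial genome held 27 thresholded peaks in 3 intervals that covered 98.5% of its 13794 bp. The replicates differed widely at the third of these peaks, with 1597 ± 938 (SD, n = 2). The mitochondrial tRNA genes WBGene00014461, WBGene00014473 and WBGene00014458 and rRNA genes WBGene00014472 and WBGene00014454 led their classes by signal, at 6864, 2944, 946, 725 and 413. With peaks over nearly the whole molecule, the lists cannot tell binding at mitochondrial genes from reads spread along it. The nuclear tRNA genes with the highest signal, chosen after their values were seen, were WBGene00022945 on II at 656, WBGene00014446 on I at 483 and WBGene00014617 on V at 439.

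Within the snRNA classes, the U1 genes sup-6 and sup-39, both known from suppressor mutations, had signals of 648 and 473, and H27M09.6 had 382. The U4 genes T11F9.15, F10D2.13 and K03B8.10 had 810.0, 205 and 130.0, and the U5 genes F32B5.9, F38E11.11 and F42C5.12 had 781, 601 and 346. The U2 genes Y57G11C.35, C47F8.9 and F11A5.14 had 479, 214 and 162, and the U6 gene F54D8.7 had 457. The names T11F9.15, F38E11.11, C47F8.9 and F54D8.7 are each shared by several copies, and some copies named C47F8.9 were unbound. Their values are those of the strongest copy: V, 11980118 to 11980261, IV, 9444642 to 9444763, II, 13829305 to 13829491, and III, 5080798 to 5080898. The SmY RNA genes smy-1, smy-8 and smy-9 had 409, 264 and 215. At smy-1 the summit lay 273 bp downstream of the start, past the end of the gene, while at smy-8 and smy-9 it lay at -43 and -65 bp. Among microRNA genes, cel-mir-8196a, cel-mir-8196b and mir-2214 led with 609, 498 and 477. Replicate means were 397 ± 5.13 for T11F9.15, 395 ± 21.7 for F32B5.9, 334 ± 60.9 for sup-6 and 213 ± 60.8 for Y57G11C.35 (SD, n = 2 each).

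By class, the median peak at SL2 RNA genes stood at percentile 94.2 of the thresholded peaks by signal (median signal 272, 20 peaks), with 94.2 ± 0.308 over the replicates (SD, n = 2). U5 genes stood at percentile 91.4, U1 at 89.96, U6 at 89.9, U4 at 89.2, SmY RNA at 87.6 and snoRNA genes at 84.0. The tRNA genes stood at percentile 62.0 (median signal 66.6, 337 peaks) and other noncoding genes at 61.6. Protein-coding genes stood below the middle, at percentile 45.7 (median signal 53.3, 639 peaks), and 78 of the 412 strongest peaks had a protein-coding gene as their first class. Two-sided permutation tests of class labels over peaks, adjusted over 14 classes, gave p = 7e-05 for SL2 RNA, tRNA, snoRNA and other noncoding genes, where the unadjusted 2e-05 is the smallest the draws can give. The permutation tests gave p = 0.000112 for U5, 0.00144 for U1 and U6, 0.00819 for SmY RNA, 0.0292 for U4 and 0.00831 for protein-coding genes. The U2 genes at percentile 76.2 (adjusted permutation p = 0.0611), piRNA genes at 41.9 (p = 0.0501), microRNA genes at 44.3 (p = 0.679) and pseudogenes at 52.2 (p = 0.846) did not pass. The calls for U4, which had 5 peaks, and for protein-coding genes were lost in single alternatives: without replicate 1 for U4 (percentile 84.9, adjusted permutation p = 0.0756) and with a window of 1000 bp for protein-coding genes (48.2, p = 0.161). Peaks are not independent replicates.

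At most bound snRNA, SL2 RNA and SmY RNA genes the nearest summit lay just upstream of the gene start. Over 70 bound genes the nearest summit had a median position of -46.5 bp (quartiles -54 and -29.25 bp), with -46.3 ± 5.30 over the replicates (SD, n = 2), and 88.6% lay within 100 bp upstream. The medians were -53 bp at U4, -52 at U5, -51 at U1, -44 at SL2 RNA, -43.5 at SmY RNA, -36.5 at U2 and -35.5 bp at U6 genes. U2 genes were spread most, with quartiles of -54.25 and 49.25 bp, 6 of 10 upstream and replicate medians of -46 and -13 bp, and at SmY RNA genes the replicate medians were -47 and -18 bp. The snoRNA genes had a median of -48 bp (-48 in both replicates), and 91 of the 102 bound genes had the summit upstream. At tRNA genes, by contrast, the median was 21 bp downstream of the start, and 165 of 367 bound nuclear tRNA genes (45.0%) had the strongest summit inside the gene, whose median length was 72 bp. Protein-coding genes had a median of -201 bp (quartiles -299 and -93.5 bp), with 700 of 807 upstream. Positions were described without a test across classes.

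**Figure D2:**
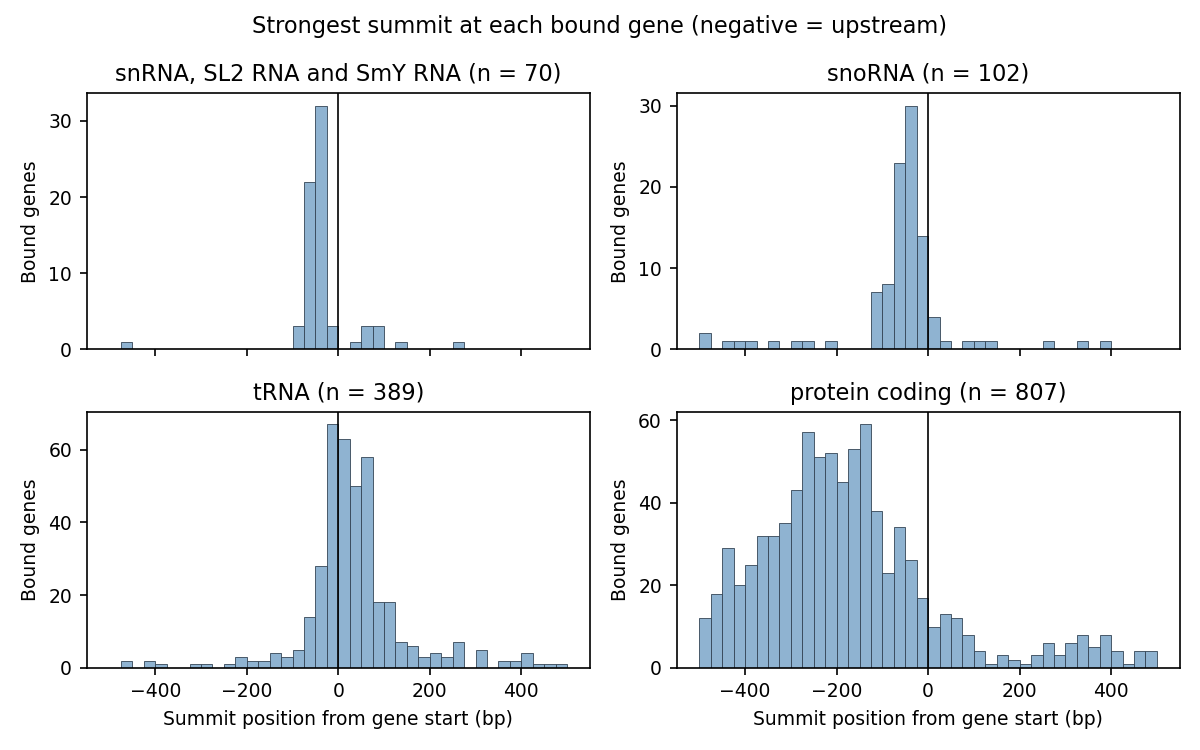
Histograms of the position of the strongest summit within 500 bp of each bound gene's start, in bp, with upstream negative and the vertical line at the start; the y axis counts bound genes. Summits at 70 snRNA, SL2 RNA and SmY RNA genes and at 102 snoRNA genes gather just upstream, those at 389 tRNA genes around and inside the short gene, and those at 807 protein-coding genes spread over the upstream window.

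Ribosomal protein genes were the protein-coding list with bound members in number. Of 81 such genes, 42 were bound (51.9%), with 49.4% ± 5.24 over the replicates (SD, n = 2), against 807 of all 19985 protein-coding genes (4.04%, 3.77 to 4.32%). The highest signals in the list were at rpl-15 (338), rpl-3 (323), rpl-20 (315), rpl-35 (242) and rpl-29 (237), with summits between -454 and -261 bp from the gene start. Among the splicing factors, snr-4, an Sm protein gene whose start lies near the U4 gene T11F9.15 and shares its peak, had 810.0, and snr-1, rsp-7, prp-8 and rsp-6 had 83.0, 60.1, 42.5 and 41.4. Bound histone genes were his-67 and his-68 (119.7, 1 peak for both), his-37 (52.7), and his-60 and his-59 (49.3, 1 peak). The germline genes rec-8, pgl-3 and puf-5 had 45.7, 44.1 and 43.2, and the SNAPc gene snpc-3.4 had 45.4.

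The odds of being bound were 26.9 times higher for ribosomal protein genes than for other protein-coding genes (two-sided Fisher exact test, p = 4.63e-37, adjusted p = 5.09e-36 over 11 lists). Without peaks near short noncoding genes, 34 ribosomal protein genes were bound (odds ratio 21.4, adjusted exact p = 1.21e-27). Of the other lists, 5 of 40 splicing factors (odds ratio 3.41, p = 0.0217, adjusted p = 0.119), 3 of 22 germline genes (3.76, adjusted p = 0.209), 5 of 72 histone genes (1.78, adjusted p = 0.408) and 1 of 16 genes of Pol III and SNAPc (1.59, adjusted p = 0.759) were bound, and these did not pass the Fisher exact test. The germline list was bound at 4 genes in replicate 1 and 0 in replicate 2, and passed by replicate 1 alone (odds ratio 5.63, adjusted exact p = 0.0488). None of the 15 piRNA pathway, 12 intestine, 11 body wall muscle and 10 neuron genes was bound. Of 160 hypodermis and collagen genes 3 were bound (odds ratio 0.452, adjusted exact p = 0.408), namely col-85 (190.4), col-54 (59.6) and col-38 (50.03).

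All protein-coding genes together were bound 2.54 times as often as under circular shifts (one-sided permutation p = 0.0001, the smallest possible, adjusted p = 0.000155), and the replicates bound 762 and 751. The strongest peaks among them were shared: besides a mitochondrial gene, cmtr-1 (signal 1639) lies beside snoRNA gene Y53F4B.47 and tim-1 (1179.6) beside sls-2.8. Of the 807 bound genes, 124 (15.4%) shared their peak with a short noncoding gene. Of the noncoding genes that led by signal, W04D2.14 and C08D8.6 likewise shared the peaks of W04D2.7 and C08D8.3. The pseudogenes with the highest signal were WBGene00045045, WBGene00018127 and WBGene00005630, at 264, 227 and 143, the first at the peak of smy-8.

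Chromosome IV held more peaks and chromosome V fewer than their lengths give. IV, where nearly all piRNA genes lie, held 451 of the 1648 peaks (27.4%), 1.57 times the number expected from its length, and 487.5 ± 10.6 over the replicates (SD, n = 2). V held 223 (0.649 times, replicates 221 ± 1.41) and II 203 (0.808 times, replicates 198.5 ± 4.95). X held 299 peaks, 1.03 times its share, of which 166 were at tRNA genes, and X carries 276 of the tRNA genes. Two-sided exact binomial tests, adjusted over 7 chromosomes, gave p = 6.75e-23 for IV, 4.04e-14 for V, 0.00136 for II and 1.65e-45 for the mitochondrial genome, whose 27 peaks were 119.1 times its share. I (0.912 times, adjusted exact p = 0.194), III (0.967, p = 0.617) and X (p = 0.617) did not pass. All of these passed with the 824 strongest peaks, at 0.727 (adjusted exact p = 0.00132), 0.804 (p = 0.0228) and 1.18 times (p = 0.0204). Without the peaks at tRNA genes, X fell to 0.574 times its share (adjusted exact p = 6.56e-14), II no longer passed (0.901, p = 0.188) and I and III stood at 1.03 and 1.07. By replicate 1 alone I passed (0.844 times, adjusted exact p = 0.01). Counting summits within 1000 bp once left the mitochondrial genome at 9.60 times its share (adjusted exact p = 0.0331). An expectation from length takes no account of copy number, so the mitochondrial excess does not by itself show binding.

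The piRNA clusters of chromosome IV were dense in peaks, while the count of bound piRNA genes lay within the wide spread of the shifts. The 2 clusters, from 4800001 to 6600000 (2658 piRNA genes) and from 13600001 to 17300000 (11510 piRNA genes), held 63 and 199 of the 451 peaks on IV. That is 262 peaks (58.1%), or 47.6 per Mb against 15.8 per Mb on the rest of the chromosome, a ratio of 3.02, with 3.16 ± 0.0736 over the replicates (SD, n = 2). Of the 262 peaks, 95 had a piRNA gene as their first class, 57 a protein-coding gene and 33 a tRNA gene, and 46 had no gene start within 500 bp. With 14168 piRNA genes in the 5.5 Mb of the clusters, a piRNA gene start within 500 bp says little. Within 100 bp of one lay 18.7% of these 262 summits. For weaker pooled peaks in the clusters, moved by 1000 to 5000 bp, that share was 42.6%. Of 15363 piRNA genes 461 were bound (3.001%, 2.74 to 3.28%), led by 21ur-7591 (742), 21ur-14704 (473, at the peak of sup-39) and 21ur-13723 (332). The summits at these lead genes lay 231, -270 and -498 bp from the gene start. The replicates bound 571 and 623 piRNA genes.

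Random placement of the peaks along IV gave a one-sided permutation p of 0.0001 for the cluster ratio, the smallest the draws can give. The bound count of piRNA genes was 1.23 times the mean of circular shifts (one-sided permutation p = 0.304, adjusted p = 0.345). The shifted count was 374 ± 164 (SD over shifts), since a shift moves clustered peaks together on or off the clusters. With such a spread only a large excess could pass, so this test sets little limit on binding at piRNA genes. The outcome depends on the threshold and the null: the 824 strongest peaks gave 0.770 times (adjusted permutation p = 0.665), independent random placement 1.20 times (adjusted p = 0.0359), and all 4814 pooled peaks at the highest q-value level 2.70 times (adjusted p = 0.000131).

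**Figure D3:**
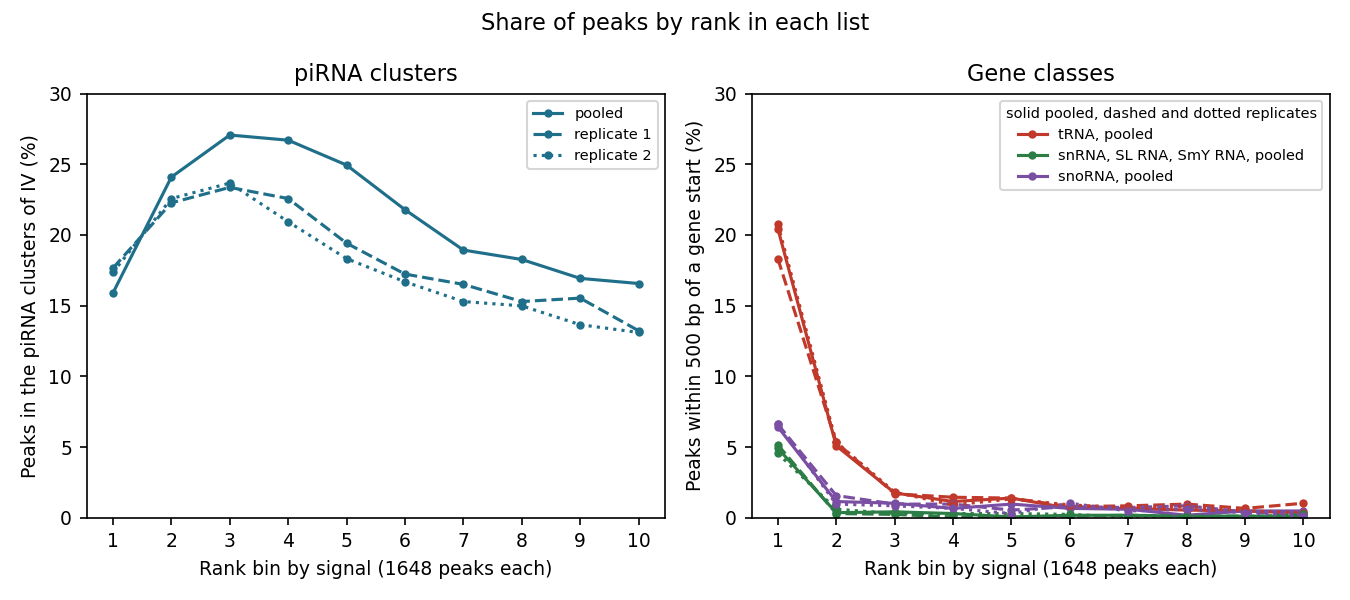
Share of peaks, in percent, by rank bin of 1648 peaks each, from the strongest (1) to the weakest (10), in the pooled list (solid) and the 2 replicates (dashed and dotted). Left, peaks inside the piRNA clusters of IV, which in the pooled list go from 15.9% in bin 1 to 27.1% in bin 3; right, peaks within 500 bp of tRNA, snRNA-type and snoRNA gene starts, where tRNA genes go from 20.4% in bin 1 to 5.10% in bin 2.

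GC-rich octamers were enriched at the summits, both at snRNA-type genes and over all peaks. The octamer GCGGAACC lay within 100 bp of the summit in 140 of 1645 peaks (8.51%) and in 6 flanking windows of the same peaks, and CGGAACCC in 142 against 8. CGGCCGAC followed with 121 against 5 and GCGGCCGA with 115 against 4. GGGTTCGA, with 123 against 10, reads like the B box inside tRNA genes, and was not among the 10 leading octamers once peaks at tRNA genes were left out. At 81 peaks of snRNA, SL RNA and SmY RNA genes, CGGAACCC was at 24 summits and 0 flanks. The octamer CTGTTTCA, the core upstream of clustered piRNA genes, was at 33 summits (2.01%) and 53 flanks (3.22%), a ratio of 0.623.

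Exact McNemar tests, two-sided, gave q = 9.31e-30 for GCGGAACC over 32817 octamers, of which 1122 passed, and q = 0.00186 for CGGAACCC at the snRNA, SL RNA and SmY RNA genes, where 3 of 15621 passed. For CTGTTTCA the exact p was 0.0265, with fewer summits than flanks. That call was lost within 50 bp of the summit (ratio 0.536, exact p = 0.0533), outside the piRNA clusters (0.533, p = 0.21), without the tRNA peaks (0.789, p = 0.366) and by replicate 1 alone (0.857, p = 0.451), while the 824 strongest peaks gave 0.222 (p = 0.000192). None of the 10310 octamers tested at 40 peaks of ribosomal protein genes passed; at an unadjusted level the leading one, GCGAGACC, was at 14 summits and 0 flanks (exact p = 0.000122).

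The replicates shared more than 50% of their strongest peaks. Of the 1648 strongest peaks of replicate 1, 921 (55.9%, 53.4 to 58.3%) had a summit of replicate 2's strongest 1648 within 200 bp, and the reverse count was 922. Of the thresholded peaks, 98.4% had a summit within 200 bp in the full list of replicate 1 and 98.4% in that of replicate 2. These 2 shares say little about agreement, since the pooled peaks come from the same replicates and each full list holds 30000 peaks. At 1595 thresholded peaks matched in both replicates, log2 signal correlated across peaks with a Spearman rho of 0.519 (bootstrap interval 0.470 to 0.560) and a Pearson r of 0.716. Of the thresholded peaks, 911 (55.3%) had a match among the strongest 1648 of both replicates. Peaks are not independent replicates. The lists on the older build ce10 gave 1614 thresholded peaks over 0.4998 Mb with 442 peaks (27.4%) on IV, and a rho of 0.518.

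The genes carried on the transgene were looked at for extra copies. Of unc-119, pie-1 and snpc-4, pie-1, whose promoter drives the transgene per the strain label, was bound, with its summit at -130 bp and a signal of 86.5 (50.3 ± 2.71 over the replicates, SD, n = 2). The pie-1 gene had 6 peaks of the pooled list within 1 kb, among them another thresholded peak 1482 bp into the gene with a signal of 40.7 (rank 1425). As a list, 1 of 3 bound genes gave an odds ratio of 11.9 (two-sided Fisher exact test, p = 0.116, adjusted p = 0.32). The rescue marker unc-119 had 8 peaks of the pooled list within 1 kb of the gene, the strongest of them 2758 bp into it with a signal of 66.8 (rank 622, inside the thresholded set). Whether the peaks at pie-1 and unc-119 come from extra copies or from binding cannot be told from the lists. The snpc-4 gene (I, 8962322 to 8966129) had 0 pooled peaks.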

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

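The pattern in this part was found in these data, and neither of its tests was chosen after its own result had been seen.

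Peaks of the pooled list that lie below the authors' threshold but at the highest q-value level entered the comparisons of bound genes only as a looser threshold, and they stood out in the piRNA clusters of chromosome IV. Of 3166 such peaks, 804 (25.4%) lay in the clusters, which make up 5.48% of the genome. A broad regional background would place summits without regard to piRNA gene starts, but 57.3% of the 804 summits lay within 100 bp of one, against 42.6% (39.6 to 45.5%) after each summit was moved by 1000 to 5000 bp within the clusters, a ratio of 1.35 (one-sided permutation p = 0.000999, the smallest that 1000 draws can give). AT-rich sequence at a scale of 10 kb would give as many peaks in 10 kb bins of the same GC content elsewhere. The density in the clusters was 8.65 times that of matched bins (95% bootstrap interval 7.52 to 9.92). The first value argues against a broad regional background, and the second against AT-rich sequence at the 10 kb scale, as the whole cause. Neither test matched base composition right at the summits, so a local sequence bias at piRNA gene starts is left open. Weak binding at piRNA gene starts is a candidate explanation, as a hypothesis found and tested on the same peaks. It would not cover the 262 thresholded peaks in the clusters, of which 18.7% lay within 100 bp of a piRNA gene start.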

How the results depend on the processing

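The alternatives that leave out tRNA peaks, other short noncoding genes or the mitochondrial genome, and the looser threshold, were chosen after the data were seen. Of 383 alternatives to 68 results, 341 kept their direction and side of the threshold or moved within error, among them every one run for U1, U2, U4, U5, U6, SL2 RNA, SmY RNA, tRNA, snoRNA and protein-coding genes bound, for chromosomes IV and V, for the cluster ratio (2.82 to 4.23) and for ribosomal protein genes. The others follow, and the cause was not tested except where named. The depth of the replicates is unknown, so how far it limits the weaker peaks cannot be given.

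With windows of 1000 bp, the fold of other snRNA genes was 4.42, the signal percentile of piRNA genes 56.1 and of protein-coding genes 48.2, and the median summit -50 bp at snoRNA, -44 at microRNA and -221 bp at protein-coding genes. The 824 strongest peaks gave a fold of 0.770 for piRNA genes and of 0.727, 0.804 and 1.18 for chromosomes I, III and X, which then passed the threshold, and odds ratios of 0 for the germline and for the Pol III and SNAPc lists, where fewer peaks leave no bound member. Random placement gave 1.20 and the looser threshold 2.70 for piRNA genes. Without tRNA peaks, I, II, III and X stood at 1.03, 0.901, 1.07 and 0.574, and CTGTTTCA at a ratio of 0.789. Summits within 1000 bp counted once gave 1.00 for III. CTGTTTCA stood at 0.536 within 50 bp and at 0.533 outside the clusters. Matched shares of the replicates were 51.2% in both directions with summits within 100 bp, 65.05% and 64.9% for the 824 strongest peaks of each, and 47.8% and 47.6% for lists of double length.

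Without either replicate in turn, I ranged from 0.844 to 0.896 and X from 0.934 to 1.01. The signal percentile ranged from 84.9 to 87.1 for U4, 45.2 to 50.6 for piRNA, 50.2 to 51.5 for microRNA and 44.4 to 45.8 for pseudogenes. The CTGTTTCA ratio ranged from 0.646 to 0.857. Odds ratios ranged from 0.731 to 1.89 for histones, 0 to 1.83 for the piRNA pathway, 0 to 5.63 for the germline list and 0 to 1.71 for Pol III and SNAPc. Replicate agreement has no such range, since it needs both replicates. No paired analysis was possible because there is 1 group.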

Other observations

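The split of the copy tests by U2 and U6 and the test for the upstream element at peaks without a gene start were chosen after the results they bear on had been seen, as were the genes mrpr-1 and yrn-1 and the motif counts below.

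Among the other noncoding genes, the RNase MRP RNA gene mrpr-1 (II, 7200233 to 7200418) had a signal of 427, with 227 ± 4.74 over the replicates (SD, n = 2) and its summit at -35 bp, beside rpr-1 at 871 with its summit at -26 bp. The Y RNA gene yrn-1 (IV, 7499508 to 7499612) had 82.8, with 43.9 ± 5.20 (SD, n = 2) and its summit at 2 bp. At ribosomal protein genes, 40 summits lay in the 500 bp before the gene start, or 0.988 per kb, against 3 in the gene bodies, or 0.0466 per kb; these counts and the odds ratio of 21.4 without peaks near short noncoding genes were first made to weigh technical explanations for that list and are given as values only.

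Peaks with no annotated gene start within 500 bp made up 404 of the 1648, with 192 of them between genes, 148 in introns and 64 in exons. The strongest of these outside the mitochondrial genome lay on IV at 991235, in an intergenic place near egrh-2, with a signal of 587 (301 ± 69.8 over the replicates, SD, n = 2), and on II at 13522035, in an intron of sre-45, with 522 (255.4 ± 55.4). CTGTTTCA was at 221 of the 804 summits below the threshold in the piRNA clusters and at 182 flanks (two-sided exact McNemar p = 0.0185, not adjusted, 1 of several sets looked at). In the scan of all octamers at these 804 peaks, 0 of 30244 passed. At the 262 thresholded peaks in the clusters CTGTTTCA ran the other way, with 25 summits and 36 flanks (exact McNemar p = 0.161).

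The first pattern weighed is the U2, U6 and SL1 RNA copies without a thresholded peak. With all pooled peaks at the highest q-value level, 11 of 23 U6, 12 of 20 U2 and 0 of 12 SL1 RNA genes were bound. Shared reads and a missing upstream element were tested for the copies unbound at the threshold. The element was a 41 bp profile built from 50 bound U1, U4, U5, SL2 RNA and SmY RNA genes. Over U2 and U6 together, unbound copies had fewer unique words of 32 bases around the start (median 74.4%, bound 86.9%) and a lower element score (difference of medians 4.19 bits); the tests compared means within class, which differed by 19.6 points (two-sided permutation p = 0.0195) and 15.5 bits (p = 0.00024). In U6 alone, bound copies had 27.7 points more unique words (permutation p = 0.0158) and scored 25.2 bits higher (p = 0.00081), so both may contribute. These tests, over U2 and U6 together and in U6 alone, treated copies as independent of each other. Groups of unbound U6 copies lie side by side, on IV from 13435785 to 13443846 and on III from 9445911 to 9449670, several with equal scores. The p-values are therefore likely too small. Neither explanation covers every copy. The unbound U6 copy at 4866811 on IV had 91.1% unique words and scored above the bound U6 median of 24.6 bits. In U2 alone the mean differences were 11.5 points (permutation p = 0.379) and 5.89 bits (p = 0.0773). The U2 medians of unique words run the other way (bound 73.5%, unbound 77.4%). Bound U2 copies had a median score of 4.43 bits, below the limit of 7.40 bits used for peaks in the next pattern. That limit came from the best score over wider windows and both strands, so it cannot show whether bound U2 copies lack the element. Shared reads and a missing or weaker element are left open for U2 copies. The median SL1 RNA copy had 0% unique words, which is consistent with reads lost to near-identical copies, and with that the lists cannot show whether SL1 RNA genes are bound.

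The next pattern is the 404 peaks without a gene start, and the same element profile lay at 132 of them (32.7%) against 6 of their flanks (1.49%, two-sided exact McNemar p = 7.58e-37), where a score above 7.40 bits counted, a limit set so that 1.03% of flanks over all peaks pass. This is not independent of the octamer scan of the same peaks, which had shown CGGAACCC, a word of the element, at 67 summits and 0 flanks. At peaks of snRNA, SL RNA and SmY RNA genes, which include the genes it was built from, the profile lay at 63.0%. It lay at 39.4% of peaks at snoRNA genes, 28.8% at piRNA genes, 6.37% at protein-coding genes and 1.20% at tRNA genes. Near-identical repeats are argued against by a median of 97.1% unique words around the 132 summits, although 14.4% of them had under 50% unique words. Diverged repeats can keep unique words, so this measure cannot decide on them. A short noncoding gene just outside the window is argued against as well, since 1.52% of the 132 summits lay within 1000 bp of one. Genes of snRNA type that the annotation lacks are a candidate explanation, as a hypothesis found and tested on the same peaks; transcription at these places was not analysed here.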
